A study of Mus musculus with 6 samples.

How the data were processed

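Gene expression was measured in fetal mouse testes at embryonic day 14.5 on a mixed B6/CD1 background. Overexpressors carried Amh-cre, which drives recombination in Sertoli cells, and 1 copy of a conditional allele that then makes the intracellular domain of NOTCH1, a constitutively active form of the receptor. Controls were littermates with the conditional allele and no Amh-cre. Each of the 6 samples was the testis pair of 1 fetus, freed from the mesonephros. Each of 3 dams gave 1 control and 1 overexpressor, so the replicates are separate animals, 3 per group. Total RNA was labelled with biotin and hybridised to 1 Illumina BeadChip array per sample, per the labels' protocols.

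Per the submitters' processing notes, GenomeStudio 2010.3 was used. Per the file headers, the deposited table gives each probe's mean bead brightness on each array, an intensity on a linear scale that is neither normalized nor background-subtracted. It also gives the deposited count of beads behind each probe, with a median of 41 to 42 beads per array, and the standard error of the bead intensity, with a median of 4.40 to 5.04% of the signal. The deposited detection p-value sets each probe against the negative controls of its array. The authors' processed table holds intensity values that equal the raw signals multiplied by 1 factor per array, from 0.855 to 1.15, so that every array has a mean of 387.2. The column medians of that table were 108.1, 112.0 and 117.5 in controls 1 to 3 and 105.0, 110.9 and 113.3 in overexpressors 1 to 3. That table is on a linear scale and is not centred per probe. The statistical test the authors used is not given in the sources used here.

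Of 45281 probes, 34885 carry 1 gene symbol in the platform annotation, 18 carry several and 10378 are unnamed there. Symbols were updated through Entrez identifiers to the GRCm38.p6 gene table, which matched 34807 probes, and 78 kept the annotation's symbol. No gene was named from a probe with several. That table served only for names, for the chromosome of a gene and for which genes are neighbours, since the files name no genome build.

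Signals were background-corrected, quantile-normalized and put on the log2 scale with neqc in limma 3.58.1 under R 4.3.3, with the background taken from the detection p-values and an offset of 16. A probe was tested when its detection p was under 0.05 on at least 3 of the 6 arrays, which kept 19889 probes. Groups were compared with limma's two-sided moderated test and Benjamini-Hochberg adjustment, and a probe counted as changed at an adjusted p under 0.05. All adjusted p-values for genes are from this fit unless stated. Of several probes of a gene, the one with the highest mean log2 intensity over the 6 arrays stands for the gene, giving 10999 genes. Where a probe was not above background on any array of a group, the fold is a bound: the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the probe's own. Log2 fold changes are overexpressor over control and are followed by their standard error.

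Before the data were examined, the comparison, the alternatives, the gene lists and the rule for naming genes were fixed. The lists were 22 for testing and 1 of sex-linked genes as a check of sex, with 459 different genes together. Named are Notch1, the 10 higher and the 10 lower genes with the largest log2 fold changes past the threshold and with the same direction in all 3 dams, every list member past the threshold, the 3 members of each list with the smallest unadjusted p, and 17 genes fixed by name. Probes with no gene name and predicted gene models, meaning genes whose symbol is a clone or LOC number such as the RIKEN names, are counted but take no place in this ranking and are not named, and any other gene is said to be chosen after its values were seen. Lists were compared with the rest of the genes by camera in limma, two-sided, 1 probe per gene, with a preset correlation of 0.01 and with a correlation estimated per list, adjusted over the 22 lists. Of the 459 list genes, sex-linked ones included, 457 were found in the gene table and 419 among the probes, and the others were not analysed here. The sex-linked list was not run in camera or used for naming.

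The replicate number is the dam in the labels, so equal numbers mark a shared litter. Littermates deviated from their group means together, with correlations across probes of 0.252, 0.426 and 0.304 for dams 1 to 3, while the other pairs of a control and an overexpressor had values from -0.279 to -0.0138. The fit has no litter term, and a fit with the dam as a block is among the alternatives. The alternatives also include no background correction, median scaling in place of quantile normalization, the authors' processed table, no filter and a stricter filter on dim probes, a trended prior variance, array weights, other thresholds, and each array left out in turn.

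The number of arrays limits the precision. With 3 against 3, an exact permutation test of a single gene cannot go below p = 0.1, so the p-values rest on the variance shared across probes in limma. The fit was tested on simulated data over 19889 probes for this comparison, with the control means and the spreads as moderated by limma. It recovered 65 of 66 probes changed by 2 on the log2 scale, 57 of 67 changed by 1 and 5 of 67 changed by 0.5, and 8 of its 135 calls were false. In a second simulation both lists that were shifted by 0.5 were called, and without a shift 0 of 22 lists were called. Both simulations draw genes independently, without the correlation within lists (up to 0.592, for the germ cell list) or the litter effect of the real arrays. The first therefore does not give the recovery or the share of false calls on the real arrays. The second does not show how often camera calls a list falsely here. Of the 9 other splits of the real arrays into 3 and 3, 8 called at least 1 list. They give no rate of false calls either, since each leaves the genotypes unequal between sides and most keep litters whole. The other splits that part all 3 litters called at most 1 list. The files and labels used here give no slide or scan batch. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.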

Results

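Expression was profiled in 6 mouse fetal testis pairs at embryonic day 14.5. Of these, 3 carried constitutively active NOTCH1 in Sertoli cells, the somatic cells that surround the germ cells, and 3 were littermate controls. The comparison asks which transcripts of the fetal testis change when NOTCH1 signalling is held on in Sertoli cells. Only overexpressors carried Amh-cre, so an effect of that transgene itself cannot be told apart from one of active NOTCH1. Between 19459 and 20285 of 45281 probes per array were above background (43.0 to 44.8%), and the median signal of detected probes was 2.16 to 2.44 times that of undetected ones. Transcripts of the Y-linked genes Eif2s3y, Kdm5d and Uty were above background on all 6 arrays with at least 1 probe each, while other probes of these genes were so on 0 arrays. Of the probes for Xist, taken with them as a check of sex, 1 was above background on 2 arrays, 1 on 1 array and the others on 0.

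Notch1, whose intracellular domain the transgene encodes, had a log2 intensity of 8.81 ± 0.19 (SD, n = 3) in overexpressors and 8.0 ± 0.31 (SD, n = 3) in controls. Its log2 fold change was 0.81 ± 0.19 (SE), higher in all 3 dams, and the adjusted p was 0.162 in limma, or 0.0505 with the dam as a block. Where the only Notch1 probe lies relative to the part that the transgene carries is not known here, so this value does not check the genotype labels. Among 11 measured NOTCH target genes, 2 rose, 0 fell and 9 did not pass. Hey1, a transcriptional repressor induced by NOTCH, rose by 1.27 ± 0.15 on the log2 scale (adjusted p = 0.00878), and Ccnd1, which encodes cyclin D1, rose by 1.66 ± 0.16 (adjusted p = 0.00476). All 3 Ccnd1 probes rose. Nrarp, a feedback inhibitor of the pathway, stood at 0.67 ± 0.13 (adjusted p = 0.0884), and adjusted over the list alone 3 genes rose. Heyl (0.38 ± 0.19) and Hes1 (0.18 ± 0.22) did not pass. Of the list 7 genes were higher and 4 lower, with a median log2 fold change of 0.18, and camera called it upward only with the preset correlation (adjusted p = 0.0143, and 0.521 with an estimated one). The lower ones, named after their values were seen, were Hey2 (-0.46 ± 0.26), Hes6 (-0.27 ± 0.14), Hes5 (-0.18 ± 0.23) and Notch3 (-0.13 ± 0.21), and none passed. Of 18 measured receptors, ligands and pathway components 0 passed, and 1, Notch1, passed when adjusted over the list alone. Dner (0.49 ± 0.17) and Numbl (0.48 ± 0.23) came next. The median of that list was -0.04, its mean was 0.08, and camera gave an upward direction with an adjusted p of 0.497. Without overexpressor 1 the Hey1 call was lost (adjusted p = 0.0567), and without overexpressor 3 the call of the target list was lost.

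**Figure D1:**
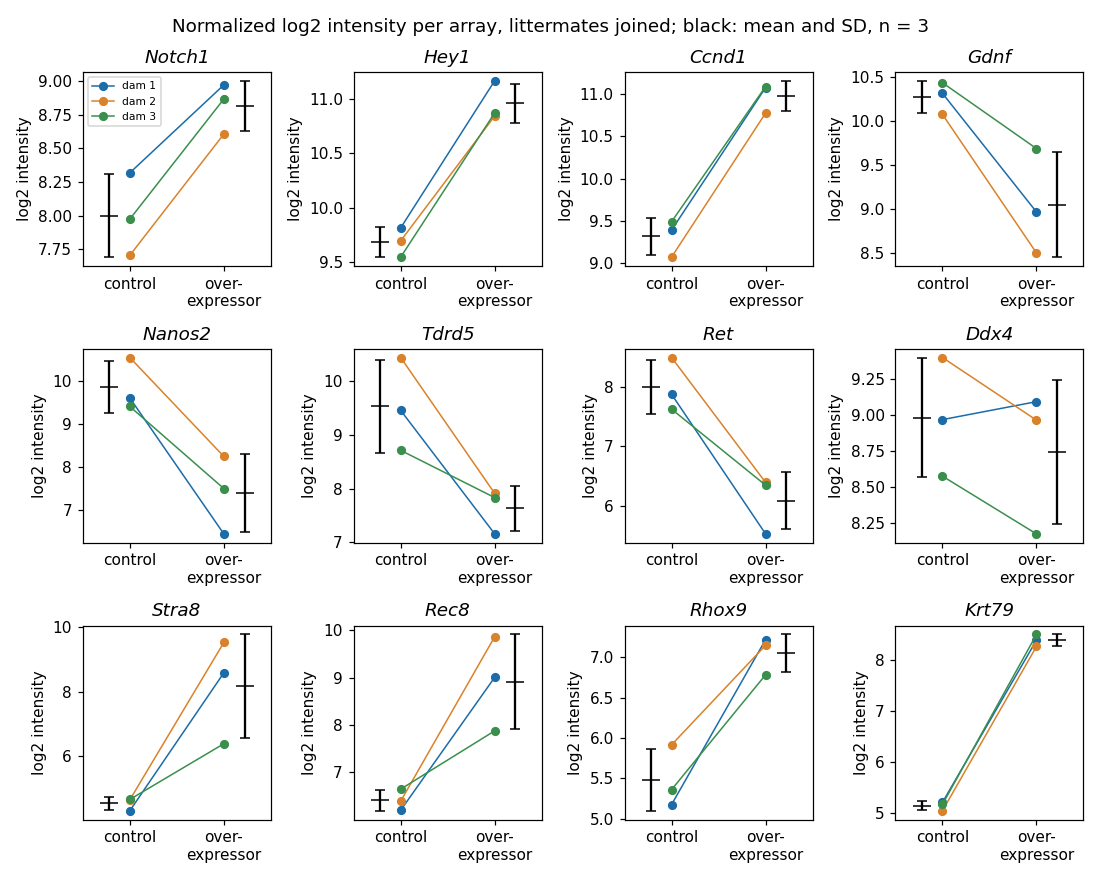
Normalized log2 intensity of 12 genes on each of the 6 arrays, with controls at the left and overexpressors at the right of each panel, lines joining the littermates of dams 1 to 3, and black bars for the group mean and SD (n = 3); axes differ between panels. Hey1, Ccnd1, Rhox9, Krt79, Stra8 and Rec8 were higher and Nanos2, Tdrd5, Ret and Gdnf lower in the overexpressor of each dam, while Ddx4 went both ways.

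In total 113 probes changed at an adjusted p under 0.05, of which 81 were higher and 32 lower in overexpressors. They include 83 genes with a symbol (3 of them clone names), 63 higher, 21 lower and 1, Nme7, with probes in both directions. Nme7 was singled out after its values were seen. All 113 probes had the same direction in the 3 dams. They were picked for a clear difference on these same arrays, so this is not separate support. Among the 113, 94 changed over 2-fold. At an unadjusted p under 0.05 there were 1889 probes, 1021 of them higher. With the dam as a block 157 probes changed, 93 higher and 64 lower, and 96 were called in both fits. The count fell to 32 without overexpressor 1, 42 without control 1, 52 without control 2, 63 without control 3 and 68 without overexpressor 2. It was 101 without overexpressor 3 and 67 with no filter on dim probes.

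The largest rises were in genes of varied function. The second in size, 4933402E13Rik, at 3.09 ± 0.28, is outside the naming rule because its name is a clone number, and was singled out after its values were seen. The epidermal keratin gene Krt79 rose by 3.25 ± 0.13 on the log2 scale (adjusted p = 7.41e-05), from 5.13 ± 0.09 to 8.39 ± 0.12 (SD, n = 3). Rnf138rt1 (3.05 ± 0.20), the DMRT family gene Dmrta1 (2.83 ± 0.16), Tpbgl (2.69 ± 0.26), the lysophosphatidic acid receptor gene Lpar3 (2.61 ± 0.36), C2cd4c (2.46 ± 0.15), Stac2 (2.33 ± 0.22), Cst12 of the cystatin family (2.10 ± 0.33) and Esyt3 (2.10 ± 0.16) also rose. Rnf138rt1, Tpbgl, Lpar3 and Stac2 were above background on 1 of 3 control arrays. Cidea, a lipid droplet protein gene, was not above background in any control and was at least 4.75-fold higher in overexpressors (adjusted p = 0.000473), or at least 2.01-fold with no background correction. The largest falls were in the galanin gene Gal (-2.92 ± 0.28), the keratin genes Krt17 (-2.55 ± 0.32) and Krt42 (-2.34 ± 0.22), Sel1l3 (-2.47 ± 0.38), Jakmip2 (-1.90 ± 0.20), the GDNF receptor gene Ret (-1.90 ± 0.29), the amino acid transporter gene Slc38a5 (-1.76 ± 0.24), Ly6g6e (-1.52 ± 0.20) and Ctsw (-1.50 ± 0.25). C1ql2 was not above background in any overexpressor and was at least 2.22-fold lower (adjusted p = 0.00919), or at least 1.33-fold with no background correction. Gal was above background in 2 of 3 overexpressors, Krt42 in 1 and Ly6g6e in 1. Near-identical family members, as among keratins and cystatins, can share probe signal. These sizes depend on the background correction: without it all 20 genes that the rule names changed less, 19 of them by over 1.5 times in fold, with Krt79 at 1.80, Rnf138rt1 at 1.52, Dmrta1 at 1.78, Gal at -1.56 and Krt42 at -1.07. The order of size turned as well: without the correction Sel1l3 (-1.83) and Krt17 (-1.65) fell further than Gal, and Slc38a5 (-1.39) further than Krt42. Ccnd1, outside these 20, stood at 1.54 or more under every alternative, and so above Rnf138rt1 in that setting. Cst12 stood at 1.03 without the correction and did not pass (adjusted p = 0.0526), and at 1.01 in the authors' processed table (adjusted p = 0.0559). With no filter on dim probes Lpar3, Cst12, Krt17, Sel1l3, Ret, Slc38a5, Ly6g6e and Ctsw did not pass (adjusted p from 0.0714 to 0.154). Of the 20 genes, Krt79, Rnf138rt1, Dmrta1, Tpbgl, C2cd4c, Cidea, Stac2, Esyt3, Gal and Krt42 passed with any 1 array left out. The highest adjusted p with 1 array left out was 0.114 for Lpar3, 0.182 for Cst12, 0.0719 for Krt17, 0.164 for Sel1l3, 0.0567 for Jakmip2, 0.136 for Ret, 0.111 for Slc38a5, 0.110 for Ly6g6e, 0.0612 for C1ql2 and 0.188 for Ctsw. The alternatives followed only the probe that stands for each gene. Second probes of Lpar3 (3.00 ± 0.33, adjusted p = 0.00702) and Ret (-1.50 ± 0.18, adjusted p = 0.00919) passed in the main limma fit with smaller adjusted p. They were not followed through the alternatives, so the lost calls of Lpar3 and Ret belong to 1 probe each.

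Genes of the male germ cell programme were lower as a list (18 measured, 12 lower and 6 higher, median log2 fold change -0.47; camera adjusted p = 0.00481, and adjusted p = 0.461 with an estimated correlation). Of them 0 rose, 1 fell and 17 did not pass, and with the dam as a block 3 fell (Ret, Nanos2 and Tdrd9). Tdrd9, named after its values were seen, stood at -1.10 ± 0.72 (adjusted p = 0.696, and 0.0221 with the block). Ret was the 1 that fell without the block, and both of its probes fell. Nanos2, an RNA-binding protein gene that drives male germ cell fate, had a log2 fold change of -2.45 ± 0.45 with an adjusted p of 0.0681, and 0.0142 with the dam as a block. Its log2 intensity was 9.85 ± 0.61 in controls and 7.40 ± 0.90 in overexpressors (SD, n = 3). Tdrd5, a piRNA pathway gene, stood at -1.90 ± 0.40 (adjusted p = 0.120, and 0.0707 with the block). Dnmt3l, a cofactor of DNA methylation in male germ cells, stood at -2.05 ± 0.75 (adjusted p = 0.438) and was above background in 2 of 3 overexpressors. Control 2 had the highest Dnmt3l log2 intensity (9.23, against 6.65 and 5.91 in controls 1 and 3), and without it the log2 fold change was -1.07. Adjusted over the list alone 0 genes rose and 4 fell, against 1 and 10 with the dam as a block, where the riser was Lefty1 (0.69 ± 0.31 without the block), named after its values were seen.

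General germ cell markers (25 measured) were lower as a list (camera adjusted p = 0.0143, and adjusted p = 0.60 with an estimated correlation), with 21 lower and 4 higher and a median log2 fold change of -0.45. By the lists as fixed, measured members shared with the male germ cell list are Tdrd1, Tdrd5, Tdrd9 and Piwil2. Those shared with the pluripotency list are Pou5f1, Lin28a and Sall4, so the calls of these lists are not separate support. Of the 25 markers 1 rose, 0 fell and 24 did not pass, and with the dam as a block 1 rose and 2 fell (Dnd1 and Tdrd9). The riser was Rhox9, a homeobox gene of the X chromosome, at 1.57 ± 0.21 (adjusted p = 0.0200, up to 0.123 with 1 array left out, and 0.0780 with no filter on dim probes). Adjusted over the list alone 2 rose and 2 fell, against 2 and 13 with the dam as a block. Dnd1, needed for germ cell survival, stood at -1.06 ± 0.24 (adjusted p = 0.167, and 0.0445 with the dam as a block). Ddx4, a marker of germ cells of both sexes, stood at -0.24 ± 0.28 and its second probe at -0.75 ± 0.28, and neither passed. Of 14 pluripotency-associated genes 8 were lower and 6 higher (median -0.13), 0 passed and 5 fell when adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.521 with an estimated correlation). Tcl1 stood at -0.86 ± 0.17, Esrrb at -0.50 ± 0.13, Dppa4 at -1.08 ± 0.29 and Pou5f1 at -0.16 ± 0.30. With the dam as a block Dppa4 passed (adjusted p = 0.0302). The call of the germ cell list was lost without control 2, overexpressor 1 or overexpressor 3 and with no filter on dim probes. That of the pluripotency list was lost without control 2, overexpressor 2 or overexpressor 3 and with array weights.

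Stra8, a gatekeeper of meiotic entry, was not above background in any control and was above it in all 3 overexpressors, at least 9.20-fold higher (adjusted p = 0.0655), or at least 3.45-fold with no background correction. Rec8, a meiotic cohesin gene, had a log2 fold change of 2.50 ± 0.42 (adjusted p = 0.0510), and Syce2, of the synaptonemal complex, one of 0.57 ± 0.13 (adjusted p = 0.176). Of 15 meiosis genes 0 passed, and 3 rose when adjusted over the list alone (camera adjusted p = 0.133). Overexpressor 3 had the lowest Stra8 and Rec8 of its group, and without it Stra8 (at least 17.0-fold higher, adjusted p = 0.00143), Rec8 (log2 fold change 3.02, adjusted p = 0.00621) and the meiosis list were called. The bound for Stra8 was 5.74-fold without overexpressor 2 and 7.95-fold without overexpressor 1. Of 14 retinoic acid genes 1 rose, 0 fell and 13 did not pass, and 3 rose when adjusted over the list alone (camera adjusted p = 0.195). Stra6, which encodes a retinol transporter, rose by 1.48 ± 0.19 (adjusted p = 0.0164, up to 0.102 with 1 array left out, and 0.0622 with no filter on dim probes). Aldh1a2, which encodes an enzyme that makes retinoic acid, stood at 0.66 ± 0.15 (adjusted p = 0.169) and the receptor gene Rarb at 0.65 ± 0.19. Cyp26b1, which encodes the enzyme that degrades retinoic acid in the fetal testis, stood at -0.18 ± 0.15 (adjusted p = 0.779).

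Fetal Sertoli cell markers moved both ways: of 24 measured, 1 rose, 1 fell and 22 did not pass, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.133). With the dam as a block 3 fell over all genes tested. The riser was Cst9, a cystatin gene of Sertoli cells, at 0.83 ± 0.13 (adjusted p = 0.0358). Cbln4 fell, with a log2 fold change of -1.20 ± 0.20 (adjusted p = 0.0474). Both calls were lost with any 1 array left out (adjusted p up to 0.169 and 0.208), and that of Cbln4 also with no filter on dim probes (adjusted p = 0.136). Hsd17b3, which encodes the last enzyme of testosterone synthesis in the fetal testis, stood at -1.0 ± 0.17 (adjusted p = 0.0541, and 0.0247 with the dam as a block). Amh, the anti-Müllerian hormone gene, stood at -1.24 ± 0.38 (adjusted p = 0.320, and 0.0749 with the block) and Sox9, which directs Sertoli cell fate, at 0.15 ± 0.18. Of 13 Sertoli-made factors that act on germ cells 0 passed (camera adjusted p = 0.418), and 1 fell when adjusted over the list alone, against 1 that rose and 3 that fell with the dam as a block. Without the block the gene that fell was Gdnf, a growth factor gene, at -1.23 ± 0.28 (adjusted p over all probes = 0.157, and 0.0505 with the block). Bmp4 stood at -0.42 ± 0.15, Tgfb3 at 0.39 ± 0.13 and Kitl at 0.37 ± 0.24. Without overexpressor 3 the Sertoli list was called downward, and Amh (adjusted p = 0.0255) and Gdnf (adjusted p = 0.0239) passed.

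Mesonephros, duct and epithelial markers, which tissue next to the testis could bring, were lower as a list (10 measured, median log2 fold change -0.19; camera adjusted p = 0.00369, and adjusted p = 0.376 with an estimated correlation). All 10 were lower, but 5 of them only by 0.02 to 0.08, among them the bright Hoxd10 (-0.05 ± 0.13; log2 intensity 10.87 in controls), singled out after its values were seen. Of them 0 rose, 1 fell and 9 did not pass, and 3 fell when adjusted over the list alone. These 3 were Ret, which is also in the male germ cell list, Lhx1 (-1.38 ± 0.31), likewise in that list, and the cadherin gene Cdh1 (-0.93 ± 0.17). A dimmer second Cdh1 probe stood at 0.22 ± 0.25. The call was lost with no filter on dim probes.

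**Figure D2:**
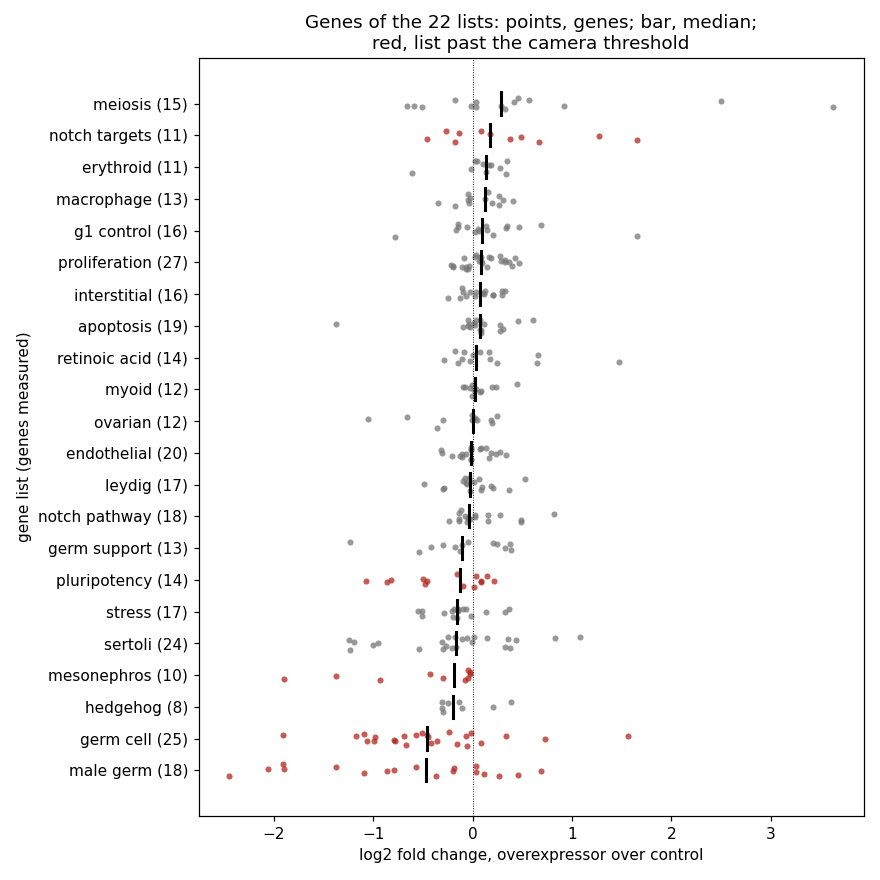
Log2 fold change (overexpressor over control) of the measured genes of the 22 lists, 1 point per gene, with a black bar at each list's median and the number of genes measured in parentheses; red marks the 5 lists past the camera threshold with the preset correlation (0 with an estimated one). The male germ cell (18 genes), germ cell (25) and mesonephros (10) lists reach furthest to the left, and Stra8 and Rec8 of the meiosis list (15) lie at the far right, where the point of Stra8 is a fitted value and not a bound.

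Genes of other cell types did not pass, with 0 calls among 17 fetal Leydig cell genes, 16 interstitial, 12 myoid, 20 endothelial, 13 macrophage and 11 erythroid genes, before or after adjustment over the list alone. Camera gave adjusted p-values of 0.948, 0.418, 0.657, 0.989, 0.271 and 0.413 for these lists. Among fetal Leydig cell genes Insl3, a hormone gene, stood at 0.07 ± 0.15, Cyp17a1, of androgen synthesis, at -0.08 ± 0.13, Pcsk6 at 0.52 ± 0.24, Gstm1 at 0.37 ± 0.15 and Aldh1a1 at -0.29 ± 0.15. Among interstitial genes Dcn (0.30 ± 0.14), Col1a1 (-0.25 ± 0.14) and Ptn (0.21 ± 0.12) had the smallest unadjusted p. Among myoid genes these were Rgs5 (0.45 ± 0.35), Tagln (0.23 ± 0.21) and Acta2 (-0.10 ± 0.12). Pecam1 (0.33 ± 0.15), Eng (-0.32 ± 0.17) and Sox17 (-0.31 ± 0.17) led the endothelial list. Lyz2 (0.41 ± 0.15), Ctss (0.26 ± 0.13) and Pf4 (0.31 ± 0.18) led the macrophage list, and Alas2 (0.34 ± 0.23), Klf1 (0.27 ± 0.30) and Kel (0.33 ± 0.39) the erythroid list. Of the Leydig and the endothelial list the median (-0.03 and -0.01) and the mean (0.01 and 0.01) differed in sign. Among 8 hedgehog pathway genes 0 passed (camera adjusted p = 0.397), with Gli3 at 0.38 ± 0.12, Ptch1 at -0.30 ± 0.15 and Gli2 at -0.24 ± 0.13.

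Of 16 regulators of the G1 phase, 1, Ccnd1, rose and 15 did not pass, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.148). Besides Ccnd1, the CDK inhibitor genes Cdkn2d (0.69 ± 0.15) and Cdkn2b (-0.78 ± 0.19) passed only there, and Cdkn1b stood at 0.15 ± 0.24. Among 27 proliferation genes 0 passed (camera adjusted p = 0.108), with Cdc6 at 0.43 ± 0.13, Cdc45 at 0.47 ± 0.18 and Tpx2 at 0.32 ± 0.14. Of 19 apoptosis and p53 response genes 0 rose, 1 fell and 18 did not pass (camera adjusted p = 0.418). Pmaip1, which encodes the pro-apoptotic protein NOXA, fell, at -1.37 ± 0.17 (adjusted p = 0.0124, and up to 0.0734 with 1 array left out). Bcl2l1 stood at 0.46 ± 0.16 and Casp9 at 0.60 ± 0.26. Among 12 genes of the ovarian pathway 0 passed, and 1 fell when adjusted over the list alone (camera adjusted p = 0.418). It was Lgr5, at -1.05 ± 0.22, while Gng13 stood at -0.66 ± 0.35 and Esr2 at -0.35 ± 0.19. The median of that list was 0.003 and its mean -0.14. Of 17 immediate-early and heat shock genes, which respond to handling of tissue, 0 passed (camera adjusted p = 0.0645), with Egr1 at -0.51 ± 0.20, Ier3 at -0.50 ± 0.17 and Zfp36 at -0.55 ± 0.21.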

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

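All alternatives below were fixed before the data were examined. The 113 changed probes kept their direction under each of the 16 of them that give probe counts, where tested (77 of 113 with the stricter filter). The dam as a block, the filters on dim probes, the trended variance and the other thresholds leave each log2 fold change as it is. Direction could turn only under the rest, and the probes had been picked for a clear difference in these data. The counts of changed, higher and lower probes and of called lists (113, 81, 32 and 5) moved by over 1.5 times as follows. With no filter on dim probes they were 67, 52, 15 and 3, with 45281 probes tested in place of 19889. A trended prior variance gave 202, 137 and 65 probes, and an adjusted p under 0.10 gave 186, 131 and 55. The authors' processed table gave 51 lower probes, and the dam as a replicate block gave 64. With a correlation estimated per list, camera called 0 lists, and 2, the male germ cell and mesonephros lists, had an unadjusted p under 0.05. With 1 array left out, changed probes ranged from 32 (without overexpressor 1) to 101 (without overexpressor 3), higher ones from 27 to 71, lower ones from 5 to 30 and called lists from 3 to 6, with fewer samples in each fit. Apart from the fewer samples, probes or lists in a fit, the cause was not tested. The block turned Nanos2, Dnd1, Dppa4 and Hsd17b3 to called and changed no other call of a list or of a gene named by the fixed rule. Of 94 named genes 27 passed, 11 of them also with any 1 array left out. Over all alternatives, 1476 values of named genes held 1344 on the same side of the threshold, 78 that lost and 49 that gained a call. Only the 27 that passed could lose a call, since the other 67 had none. The 1.5-fold minimum could change no call, since all 113 probes changed over 1.5-fold. Directions turned for 4 genes, none of them called, with 1 array left out, where log2 fold changes ranged from -0.12 to 0.30 (Cdkn1b), -0.40 to 0.15 (Pou5f1), -0.44 to 0.048 (Ddx4) and -0.0076 to 0.37 (Hes1). Lists gained calls as well: the stress list under 4 alternatives (adjusted p from 0.00574 to 0.461 over its 17), the proliferation list under 3 (0.0347 to 0.60), and the Sertoli, meiosis and G1 lists under 1 each. Uncalled lists turned direction too. Camera's adjusted p was then 0.963 for the Leydig list with the dam as a replicate block and 0.963 for the NOTCH pathway list with the stricter filter. For the endothelial list it was 0.929 with no background correction, 0.966 with a trended variance, 0.804 with array weights and 0.806 with all probes of the genes. With 1 array left out the adjusted p ranged from 0.250 to 0.919 (endothelial), 0.0758 to 0.734 (erythroid), 0.232 to 0.908 (Leydig), 0.443 to 0.908 (myoid) and 0.236 to 0.976 (NOTCH pathway). The planned look at other Notch1 probes was not run, since 1 probe was given, and the 1.5-fold minimum has no meaning for lists. Signals of detected probes were 2.16 to 2.44 times those of undetected ones, which limits what can be seen of dim genes, and with no background correction the folds of the 20 genes of largest change were 1.29 to 2.89 times smaller.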

Other observations

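All genes and tests in this part were chosen after their values were seen. Of 8 measured cystatin family genes 3 rose, and 5 did not pass. Besides Cst9 and Cst12, Cstdc1 rose by 1.71 ± 0.18 on the log2 scale (adjusted p = 0.00619), while Cst11 stood at 0.74 ± 0.13 (adjusted p = 0.0556) and Cst3 (0.01 ± 0.16), Cstb (-0.09 ± 0.13), Cstdc4 (0.40 ± 0.60) and Cstdc5 (-0.06 ± 0.70) did not pass either. Of 16 keratin genes 1 rose, 2 fell and 13 did not pass. Other genes that rose were Vdr, the vitamin D receptor gene, at 1.18 ± 0.16 (adjusted p = 0.0164), with all 3 of its probes past the threshold, the metallothionein gene Mt1 (1.41 ± 0.20), the riboflavin transporter gene Slc52a3 (1.67 ± 0.19), and Dbp (1.17 ± 0.13), of circadian output. The forkhead gene Foxq1 (-1.48 ± 0.19) and the growth factor gene Pdgfa (-1.06 ± 0.17) fell, though with the dam as a block Pdgfa did not pass (adjusted p = 0.0548).

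Changed probes were compared with those of other splits of the 6 arrays into 3 and 3. The real split gave 113 and the highest of the others 3, and 1 of the 10 splits, the real one, reached the real count. For called lists the real split gave 5 and the highest other 7, and 2 of 10 splits reached the real number. The split with 7 follows litters, with both littermates of dam 3 on one side and both of dam 2 on the other. With the dam as a block the real comparison also gave 5 lists with the preset correlation, but none with an estimated one (lowest camera adjusted p = 0.469). Among the 4 splits that part all 3 litters, the others gave at most 0 probes and 1 list. With 10 splits the share cannot fall under 0.05, so they are too few to say whether chance is excluded.

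The male germ cell list was called lower only with the preset correlation (camera adjusted p = 0.461 with an estimated one), with 12 of its 18 genes lower and 6 higher. Of 25 general germ cell markers, which share Tdrd1, Tdrd5, Tdrd9 and Piwil2 with that list, 21 were lower. Fewer germ cells and less advanced germ cells are candidate explanations. The 5 genes of the germ cell and male germ cell lists that fell when adjusted over a list alone (Tdrd5, Dnd1, Ret, Nanos2 and Lhx1) had a median log2 fold change of -1.90, against -0.42 (SD 0.68) for 17 other germ cell markers outside the male, pluripotency and meiosis lists; Ret and Lhx1 are also mesonephros markers, but 5 of the 10 genes of that list stood between -0.08 and -0.02 (Hoxd10 at -0.05 ± 0.13), and less of that tissue was not tested as a cause. The markers' medians were -0.34 and -0.37 against -2.30 and -2.18 in dams 1 and 2, but -0.52 against -0.88 in dam 3. The 5 genes were picked for their fall in these data and the 17 markers leave them out, so a gap was fixed in advance. Its size therefore decides nothing, and a loss of germ cells stays open. Across the 39 genes of both lists, the Spearman rho between the fold change and a dam's difference from the other dams, averaged over genotypes, was -0.67 for dam 2 (6 of 10000 random gene sets had a value as low), 0.66 for dam 1 and 0.46 for dam 3, but genes are not independent replicates and the erythroid list gave a lower value for dam 2 (-0.73), so the relation does not single out germ cell stage. Stra8 and Rec8 exceeded the values that relation gives by at least 6.61 of their standard errors, which decides nothing while the relation itself is unspecific. A loss of germ cells alone would not raise Stra8 or Rec8, which were higher in all 3 dams, though neither passed the threshold. For the lower genes a delay, a loss of germ cells and another effect of the genotype cannot be told apart here.

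Nme7 had 7 tested probes, of which 3 rose (1.36 to 1.65), 1 fell (-1.85 ± 0.15, adjusted p = 0.00326) and 3 did not pass. In the GRCm38.p6 gene table Nme7 neighbours Atp1b1, which rose by 1.28 ± 0.13 (adjusted p = 0.00563). The 3 probes may read Atp1b1 transcripts: their mean exceeded that of Atp1b1 by 0.19. For 1 such probe against Atp1b1, with the estimates taken as independent, the standard error is 0.20. But 46 of the 77 other higher probes also lay within the distance from Atp1b1 that this standard error allows. The value therefore decides nothing, and the probe that fell is not addressed by it. No biological explanation was tested.

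Changed genes lay on the X chromosome more often than chance placement would give, at 9 of 83 changed genes against 383 of 10984 tested genes with a position. The odds ratio was 3.42 (95% confidence interval 1.49 to 6.93), and Fisher's exact p, two-sided, was 0.00234, or 0.0467 after adjustment over 20 chromosomes. Of the 9, 8 rose, among them Rnf138rt1, Rhox9, Mid1ip1 (1.45 ± 0.16), Map7d3 (1.08 ± 0.16) and Capn6 (1.04 ± 0.16), and Slc38a5 fell. With the dam as a block, and a gene counted only by the probe that stands for it, 12 X-linked genes changed (Fisher's exact test, adjusted p = 0.0132). Without the block the excess narrowly passed, and a gene there counted as changed when any of its probes passed, which favours genes with more probes. That rule added no X-linked gene, since all 9 passed by the probe that stands for them (limma adjusted p from 0.000936 to 0.0498). Genes are not independent, and an effect of the genotype on X-linked genes of germ or Sertoli cells was not tested.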
